A study of Arabidopsis thaliana with 6 samples.

How the data were processed

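The series holds 6 RNA sequencing libraries from whole seedlings of the Columbia (Col) accession of Arabidopsis thaliana, the small crucifer used as a model plant. Seedlings grew for 12 days on agar with nitrogen-free mineral salts and 0.5% sucrose. The sole nitrogen source was 5 mM NH4NO3 in 3 samples and 5 mM glutamine (Gln) in 3 samples, per the labels. Total RNA was made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. That kit does not mark the strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart.

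The deposited table gives 1 value per gene and library in RPKM, reads scaled by gene length and library size, with library sizes scaled by the trimmed mean of M values (TMM), per the file headers and name. The TAIR10 build and SAMtools are named in the submitters' processing notes. The aligner, the read counter, their versions and the annotation release are not given in the sources used here. The table also lists a length in kilobases per gene and, per the file headers, a maximum multi-read ratio, a fraction from 0 to 1 that the headers do not define. By its name it is the largest share of a gene's reads that map to several places, and 1175 genes exceeded 0.1. None of the values was 0, because each value times the gene length equalled a read number plus 0.5, times 1 step per library. The read numbers implied in this way were whole within 0.05 for 98.1% to 98.8% of values up to 20 reads. They summed to 31517316, 31980649 and 28654433 reads in genes for NH4NO3 replicates 1 to 3, and to 30269306, 35421727 and 34036257 for Gln replicates 1 to 3. The implied TMM factors lay between 0.986 and 1.03. Because the main values are RPKM, no test made for counts was the main test. A count test, listed before the data were examined for the case that whole reads could be recovered, was not run either, and voom weights on the implied reads were tried in its place.

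Of the 33602 gene identifiers, 32835 matched the RefSeq annotation of TAIR10.1, which gave symbols, products and coordinates. The table itself carries no coordinates, and all positions below are those of TAIR10.1, counted from 1. In 20 of the 491 members of the fixed gene lists, the symbol was absent from that annotation. No such locus carried a different gene's symbol, and all were kept by locus.

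All genes with a mean of at least 1 RPKM over the 6 libraries, 19284 in number, were tested with limma 3.58.1 in R 4.3.3. The test used log2(RPKM + 1), a mean-variance trend, 2-sided p-values and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Fold changes are Gln minus NH4NO3 on the log2(RPKM + 1) scale, which understates the change of genes with low values. Before the data were examined, 25 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 25 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Named genes were the 10 higher and the 10 lower genes with the largest fold change, among called genes with a mean of at least 5 RPKM and no overlap between the groups. Also named, whatever their result, were 19 genes of nitrogen uptake and assimilation, and for each list up to 4 called members with the largest change.

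The libraries were compared before averaging. Pairs within a group differed by 3.59 to 7.27 times the variance that counting error alone gives, so no library was a second copy of another. Among genes with 1 to 100 reads, an even read number was found in 45.0% of genes in NH4NO3 replicate 2 (95% exact binomial interval 43.8% to 46.2%). In the other 5 libraries it was found in 58.5% to 61.4%. NH4NO3 replicate 2 therefore differs from the others in how its reads were counted or made. The counts of genes called, of genes at 2-fold and of list members called were also computed without it. Counts at 4-fold, of genes without overlap, of families and of glucosinolate branches were not. Counting intervals assume that reads are independent molecules and cover counting error only. Replicates carry numbers in the labels but no statement that they came from separate plates or days, so p-values measure the spread between these samples, which may be technical. Whether equal replicate numbers pair the samples was also checked.

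The test was tried on simulated reads for the same genes, libraries and groups, with 200 genes changed. All genes were given the same dispersion, the median over more highly expressed genes, and no library effect was added. The recovery of noisier genes is therefore likely overstated. Only these 200 genes were changed, whereas 41.2% of the genes tested were called in the real data. The Benjamini-Hochberg adjustment was therefore stricter in the simulation, so the recovery of small changes may be understated. At a simulated change of 1.25-fold, 18% of 50 genes were recovered, with 88% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. Of 19216 genes tested in the simulation, 13 unchanged genes were called. Camera called the 1 shifted list and 0 of 25 random lists. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.79 (photosynthesis). The simulation therefore cannot tell how often camera calls a list of co-regulated genes falsely. Alternatives changed the pseudocount, the filter on low values, the scaling, the variance model, the threshold, the replicate block, the list test and the libraries used. Those added after seeing the data were voom weights on the implied reads, library totals in place of TMM, genes without shared reads, and lists without members lacking a symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.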

Results

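Whole seedlings were compared after 12 days on 5 mM Gln or 5 mM NH4NO3 as the only nitrogen source. The comparison asks which transcripts depend on the form of nitrogen supplied. Because the Gln medium held no NH4NO3, an effect of Gln cannot be told apart from the absence of nitrate and ammonium, for any result below. Each group held 3 libraries, with 28654433 to 31980649 reads in genes for NH4NO3 and 30269306 to 35421727 for Gln. The libraries separated by nitrogen source along the first principal component, which held 74.5% of the variance. Correlations of log2 values across genes were 0.990 to 0.994 within groups and 0.959 to 0.966 between groups. Chloroplast-encoded transcripts took 0.135% of reads in NH4NO3 replicate 1 and 0.0277% to 0.0656% in the other 5 libraries. The 10 most abundant genes took 7.40% to 8.30% of reads in NH4NO3 and 5.69% to 6.88% in Gln.

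Seedlings on Gln had far lower transcript levels of the nitrate assimilation enzymes and higher levels of salicylate defence genes, PR1 most of all, than seedlings on NH4NO3. NIA1, a nitrate reductase, fell from 126 ± 8.10 to 2.87 ± 0.390 RPKM (mean ± SD, n = 3 per group here and below). PR1, a secreted pathogenesis-related protein and the standard marker of the salicylate response, rose from 5.37 ± 2.18 to 234 ± 53.9 RPKM. In all, 7942 of 19284 genes tested, or 41.2%, were called by limma at an adjusted p under 0.05. Of these, 4126 were higher and 3816 lower in Gln. Among the 772 genes that also changed at least 2-fold, 603 were higher and 169 lower, and at 4-fold the numbers were 68 and 19. The 3 values of each group did not overlap for 53.6% of the genes tested, where chance gives 10%.

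The other genes with the largest increases included PUB54, a U-box protein, from 1.79 ± 0.606 to 33.3 ± 10.8 RPKM, and AT1G26390, a berberine-type FAD-binding oxidase, from 21.0 ± 5.29 to 261 ± 58.9 RPKM. The ERF transcription factor gene RAP2.6 rose from 5.05 ± 0.284 to 63.8 ± 1.3 RPKM, a log2 fold change of 3.42 ± 0.07 (SE). A cupin gene, AT5G38910, rose from 22.3 ± 6.83 to 221 ± 21.9 RPKM, and a protein phosphatase 2C gene, AT4G32950, from 2.62 ± 0.711 to 31.6 ± 2.68 RPKM. Genes that were almost silent on NH4NO3 also rose. AT3G13630, of no known product, went from 0.143 ± 0.108 to 24.3 ± 9.81 RPKM. The non-coding gene AT3G15536 and the neighbouring AT3G15534, about which the annotation says nothing and which do not overlap, reached 10.8 ± 2.43 and 11.6 ± 2.09 RPKM from 0.310 ± 0.190 and 0.572 ± 0.517. AT2G44240, a DUF239 protein, had 3 reads over the 3 NH4NO3 libraries and 2355 over the 3 Gln libraries, a ratio of 719 after scaling (95% counting interval 246 to 3487). Genes with the largest decreases, besides those of the nitrate response list described next and ERF105, given with the stress genes, were ASN2, AT1G68238 (17.9 ± 2.81 to 0.845 ± 0.237 RPKM), AT4G33960 (16.6 ± 1.55 to 1.29 ± 1.00 RPKM) and AT5G62720, a predicted membrane protein of the HPP family (86.5 ± 1.74 to 15.3 ± 0.530 RPKM).

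Genes that respond to nitrate were lower in Gln. Of 28 list members tested, 21 fell, 4 rose and 3 did not pass the test. NIA1 (AT1G77760) lies on chromosome 1 at 29235721 to 29239484, minus strand, and had a log2 fold change of -5.04 ± 0.09 (limma adjusted p = 3.2e-09). The second nitrate reductase gene, NIA2 (AT1G37130, chromosome 1, 14158452 to 14161938, plus strand), fell from 390 ± 2.46 to 35.4 ± 4.45 RPKM. NIR1, the nitrite reductase gene (AT2G15620, chromosome 2, 6810395 to 6812941, plus strand), fell from 101.2 ± 3.62 to 22.7 ± 1.14 RPKM. Of the genes on the list that encode regulators, HRS1 fell from 28.8 ± 0.649 to 2.42 ± 0.363 RPKM, BT1 from 110 ± 12.3 to 13.3 ± 1.23 RPKM and BT2 from 103 ± 15.2 to 7.52 ± 0.717 RPKM. The dual-affinity nitrate transporter NRT1.1 fell less, from 78.5 ± 2.19 to 42.6 ± 5.20 RPKM. NRT2.1, a high-affinity nitrate transporter on the same list, went the other way and rose from 3.91 ± 1.23 to 24.3 ± 2.16 RPKM. The median log2 fold change of the list was -0.58, and camera gave an adjusted p of 5.3e-09 with the preset correlation and an adjusted p = 0.080 with an estimated correlation. Adjusted over the list alone, 22 members were lower and 4 higher. After quantile normalization 22 were lower and 2 higher, adjusted over all genes.

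**Figure D1:**
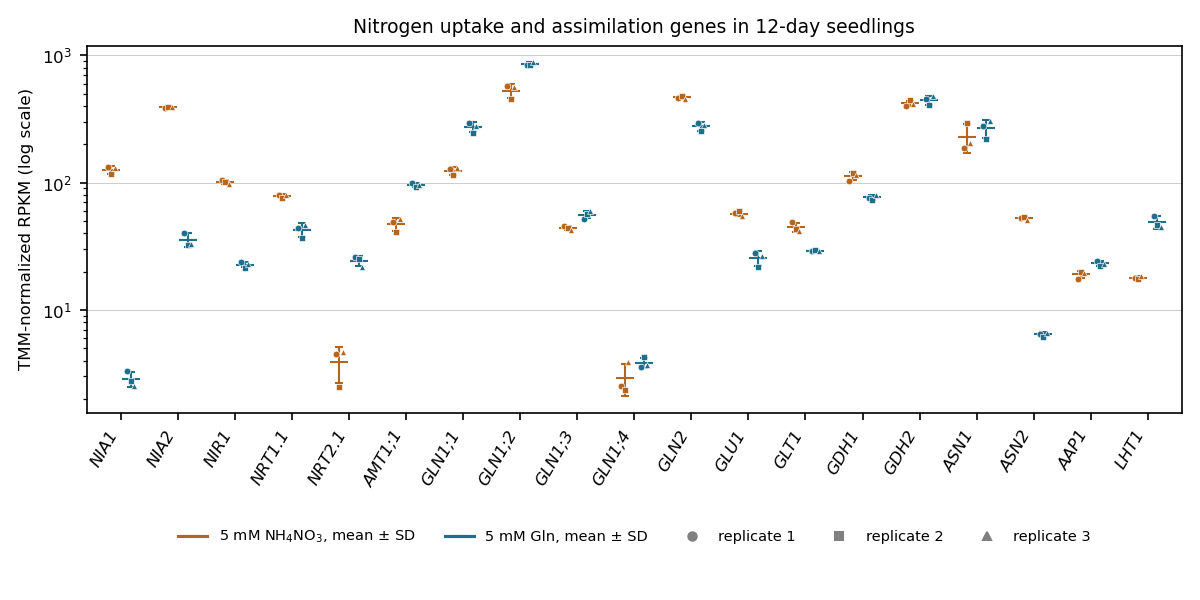
TMM-normalized RPKM on a log axis for 19 genes of nitrogen uptake and assimilation in seedlings on 5 mM NH4NO3 (brown) or 5 mM Gln (blue); points are the 3 replicates, and horizontal ticks with bars are the mean ± SD. NIA1, NIA2, NIR1 and ASN2 lie far lower in Gln, NRT2.1 and LHT1 lie higher, and GLN1;4, GDH2 and ASN1 did not pass the test.

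Transporters that take up ammonium and urea were higher in Gln. Of 7 tested members of the nitrogen starvation and ammonium or urea uptake list, 5 rose, 1 fell and 1 did not pass. The urea transporter DUR3 rose from 9.09 ± 1.28 to 24.7 ± 1.38 RPKM, and the ammonium transporters AMT1;1 and AMT2;1 from 47.3 ± 5.68 to 96.0 ± 3.25 RPKM and from 18.3 ± 1.71 to 35.7 ± 2.95 RPKM. AMT1;3 rose by 0.61 on the log2 scale. The list had a median log2 fold change of 0.61 and a camera adjusted p of 0.0061 (adjusted p = 0.50 with an estimated correlation), and with no filter on low values 8 of 11 rose and 2 fell. No member was lower without NH4NO3 replicate 1 or 3 or without Gln replicate 2 or 3.

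The glutamine synthetase and glutamate synthase genes moved in different directions. The cytosolic glutamine synthetase genes GLN1;1, GLN1;2 and GLN1;3 rose, GLN1;1 from 124 ± 8.26 to 273 ± 24.2 RPKM, GLN1;2 from 529 ± 63.3 to 853 ± 25.4 RPKM and GLN1;3 from 44.1 ± 1.63 to 56.1 ± 3.75 RPKM. GLN2, the plastid isoform, fell from 467 ± 12.2 to 276 ± 22.0 RPKM. Both glutamate synthase genes that were named in advance also fell, the ferredoxin-dependent GLU1 from 57.1 ± 2.39 to 25.5 ± 3.26 RPKM and the NADH-dependent GLT1 from 44.6 ± 3.83 to 29.1 ± 0.214 RPKM. The asparagine synthetase gene ASN2 fell from 52.3 ± 0.990 to 6.42 ± 0.245 RPKM, whereas ASN1 was at 228 ± 58.9 RPKM in NH4NO3 and 266 ± 43.2 RPKM in Gln and did not pass the test (adjusted p = 0.29). Without NH4NO3 replicate 2 the adjusted p of ASN1 was 0.032, the lowest of a range up to 0.78 over all alternatives. GDH1, a glutamate dehydrogenase gene, fell from 112 ± 8.25 to 76.4 ± 3.75 RPKM, and GDH2 was at 420 ± 20.17 and 446 ± 36.6 RPKM (adjusted p = 0.44). GLN1;4 was at 2.92 ± 0.826 and 3.84 ± 0.376 RPKM, with an adjusted p of 0.11 that became 0.014 without NH4NO3 replicate 3, the lowest of a range up to 0.31 over all alternatives. Of 24 tested members of the list, 5 rose, 7 fell and 12 did not pass. Its mean log2 fold change was -0.11 and the camera direction was down (adjusted p = 0.61), while its median was 0.04. Fry called this list (fry adjusted p = 0.0079). The median was -0.01 without Gln replicate 3, -0.05 after quantile normalization and -0.02 with no filter on low values. Adjusted over the list alone, 6 were higher and 7 lower.

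Among amino acid transporters, 10 of 20 rose, 1 fell and 9 did not pass. LHT1, a broad-range importer of amino acids, rose from 17.9 ± 0.564 to 48.7 ± 5.60 RPKM, and the exporters UMAMIT14 and UMAMIT18 from 2.25 ± 0.118 to 10.9 ± 2.88 RPKM and from 31.0 ± 1.02 to 52.7 ± 7.21 RPKM. CAT1, a cationic amino acid transporter, rose from 1.98 ± 0.118 to 6.92 ± 1.85 RPKM, and the permease AAP1 from 19.0 ± 1.22 to 23.2 ± 1.11 RPKM. Camera gave an adjusted p of 0.036 (adjusted p = 0.23 with an estimated correlation), which became 0.061 without NH4NO3 replicate 3 and 0.075 with a filter at a mean of at least 5 RPKM, and ranged from 0.0079 to 0.23 over all alternatives. Without NH4NO3 replicate 2 the number of higher members was 6, and 2 were lower without NH4NO3 replicate 2 or 3 or without Gln replicate 1. Adjusted over the list alone, 10 were higher and 2 lower. Genes of amino acid catabolism and low energy went both ways, with 3 of 25 higher, 11 lower and 11 not called (camera adjusted p = 0.077). PRODH2, a proline dehydrogenase, and MGL, a methionine gamma-lyase, rose from 11.9 ± 0.987 to 23.8 ± 2.68 RPKM and from 16.0 ± 0.565 to 29.2 ± 3.31 RPKM. TPS10 fell from 39.0 ± 2.34 to 22.7 ± 1.27 RPKM and DIN10 from 342 ± 49.5 to 216 ± 14.6 RPKM. Adjusted over the list alone, 4 members were higher and 12 lower. The number of lower members was 6 without NH4NO3 replicate 2, without NH4NO3 replicate 3 or without Gln replicate 2, and 5 were higher without NH4NO3 replicate 2. The list passed the threshold without NH4NO3 replicate 1 (adjusted p = 0.0083) and without Gln replicate 1 (adjusted p = 0.035). It also passed with no filter on low values (0.043), quantile normalization (0.032), array weights (0.022) and without members lacking a symbol (0.017), in a range from 0.0083 to 0.70 over all alternatives.

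Both arms of the defence response were higher in Gln. In the salicylate list 19 of 20 genes rose and 1 did not pass. PR1 (AT2G14610, chromosome 2, 6241640 to 6242541, minus strand) had a log2 fold change of 5.24 ± 0.23 (limma adjusted p = 6.0e-07). PR2, a beta-1,3-glucanase, rose from 1.52 ± 0.901 to 10.7 ± 3.32 RPKM, PBS3, an enzyme of salicylate synthesis, from 7.72 ± 0.637 to 30.9 ± 7.77 RPKM, and WRKY54 from 2.79 ± 0.282 to 11.9 ± 1.99 RPKM. The median log2 fold change was 0.85 and the camera adjusted p 8.0e-10 (adjusted p = 0.23 with an estimated correlation). In the jasmonate and ethylene list 15 of 21 genes rose, none fell and 6 did not pass. The allene oxide cyclases AOC1 and AOC2, enzymes of jasmonate synthesis, rose from 50.8 ± 9.81 to 222 ± 2.02 RPKM and from 98.5 ± 9.15 to 353 ± 14.0 RPKM. The defensin PDF1.2 rose from 1.83 ± 0.609 to 11.8 ± 3.89 RPKM and PDF1.2c from 0.500 ± 0.410 to 3.76 ± 1.1 RPKM. AOC1 with AOC2 and PDF1.2 with PDF1.2c are near-identical copies, and their separate values are uncertain if reads were shared between them, although their deposited multi-read ratios are 0. The list had a median log2 fold change of 0.83 and a camera adjusted p of 8.2e-09 (adjusted p = 0.17 with an estimated correlation).

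Rapidly induced stress transcription factors were mostly lower in Gln. Of 17 tested, 11 fell, 3 rose and 3 did not pass. ERF105 fell from 72.2 ± 23.4 to 11.3 ± 1.55 RPKM, and the cold-response regulators DREB1C and DREB1B from 34.9 ± 13.8 to 6.38 ± 1.96 RPKM and from 7.52 ± 3.06 to 1.05 ± 0.615 RPKM. RAP2.6, described above, is on the same list and rose. Within the NH4NO3 group, NH4NO3 replicate 2 had the highest value for 14 of the 17 genes, and without it 9 were lower and 4 higher. The median log2 fold change was -0.63, with a camera adjusted p of 0.020 (adjusted p = 0.64 with an estimated correlation), and fry did not call the list (adjusted p = 0.80). All 965 bases of ERF105 overlap AT5G51180 on the other strand, which had a mean of 19.2 RPKM over the 6 libraries. Of 13 genes of the abscisic acid and water deficit list, 8 rose, 1 fell and 4 did not pass. RD29A rose from 43.5 ± 5.47 to 169 ± 15.1 RPKM, KIN1 from 11.4 ± 0.215 to 41.1 ± 4.3 RPKM, RD20 from 2.24 ± 0.293 to 6.48 ± 1.42 RPKM and HAI1, a phosphatase, from 1.96 ± 0.332 to 5.03 ± 0.154 RPKM. The median log2 fold change of this list was 0.61, with a camera adjusted p of 0.0025 (adjusted p = 0.17 with an estimated correlation), and adjusted over the list alone 8 were higher and 2 lower. Without NH4NO3 replicate 1, 2 were lower.

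Root hair genes were higher and shoot genes lower in Gln. All 11 root hair genes rose, among them PRP3, a cell wall protein, from 9.96 ± 1.01 to 28.5 ± 1.79 RPKM, and the expansins EXPA7 and EXPA18 from 5.01 ± 0.458 to 14.5 ± 2.54 RPKM and from 6.39 ± 0.841 to 16 ± 3.9 RPKM. PRPL1 rose from 7.11 ± 0.823 to 17.61 ± 3.09 RPKM. The median log2 fold change of root hair genes was 1.14 (camera adjusted p = 2.8e-07; adjusted p = 0.23 with an estimated correlation). Genes of other root cell types had a median of 0.24, with 5 of 14 higher, 1 lower and 8 not called (camera adjusted p = 0.33). This median was 0.06 without Gln replicate 3, 0.36 without Gln replicate 1, 0.14 with a pseudocount of 5 and 0.11 with no filter on low values. CASP4, of the endodermis, rose from 6.46 ± 1.13 to 10.2 ± 2.31 RPKM (adjusted p = 0.013, and 0.053 without NH4NO3 replicate 3, in a range from 0.0098 to 0.053 over all alternatives). PHO1 and MYB36 rose from 24.2 ± 2.47 to 36.4 ± 7.01 RPKM and from 4.18 ± 0.0617 to 6.45 ± 0.618 RPKM, and the aquaporin TIP2;3 fell from 31.7 ± 4.56 to 18.6 ± 4.98 RPKM. The number of higher members of this list was 2 without NH4NO3 replicate 3 and 3 without NH4NO3 replicate 2, without Gln replicate 2 or without Gln replicate 3, and 3 were lower without Gln replicate 2.

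Of 12 genes of the shoot epidermis, stomata and leaf polarity, 10 fell and 2 did not pass. SPCH, which starts the stomatal lineage, fell from 4.1 ± 0.358 to 1.4 ± 0.320 RPKM, and the guard cell genes KAT1 and MYB60 from 10.5 ± 0.810 to 5.38 ± 1.09 RPKM and from 10.9 ± 0.243 to 6.49 ± 0.427 RPKM. AS1 fell from 14.6 ± 1.83 to 9.16 ± 0.869 RPKM, with 330 of its bases overlapping AT2G37620. This list had a median log2 fold change of -0.56 and a camera adjusted p of 1.5e-05 (adjusted p = 0.17 with an estimated correlation). Of 51 genes of photosynthesis and chlorophyll synthesis, 42 fell and 9 did not pass. The light-harvesting genes LHCB2.1 and LHCB4.2 fell from 899 ± 91.9 to 471 ± 60.4 RPKM and from 1264 ± 141 to 707 ± 88.0 RPKM. LHCB1.1, which has near-identical copies and is therefore uncertain, fell from 3616 ± 369 to 1984 ± 391 RPKM. GUN4, a regulator of chlorophyll synthesis, fell from 44.1 ± 6.01 to 24.2 ± 2.80 RPKM and overlaps AT3G59410 over 946 bases. The median was -0.44, or -0.24 after quantile normalization, with a camera adjusted p of 8.0e-10 (adjusted p = 0.61 with an estimated correlation), and 25 members were lower without NH4NO3 replicate 2 and 1 was higher without Gln replicate 2. With no filter on low values 21 of the 51 were lower, and after quantile normalization 30 were lower and 2 higher. Of 23 cell cycle genes 6 fell and 17 did not pass. CYCA1;1 fell from 4.66 ± 0.140 to 2.77 ± 0.606 RPKM, CDC20.1 from 19.4 ± 2.95 to 12.8 ± 1.81 RPKM, CDC20.2 from 10.8 ± 1.39 to 6.54 ± 1.92 RPKM and CYCD3;1 from 12.5 ± 0.835 to 8.86 ± 1.21 RPKM. CDC20.1 and CDC20.2 share reads, with multi-read ratios of 0.212 and 0.211, and CYCD3;1 overlaps the abundant AT4G34150 over 40 bases, so all 3 are uncertain. Camera gave an adjusted p of 0.018 for this list (adjusted p = 0.67 with an estimated correlation), and fry did not call it (adjusted p = 0.19). The camera adjusted p became 0.066 without NH4NO3 replicate 1, where 3 members and not CDC20.2 were called, and 0.10 without Gln replicate 1, where the list's median log2 fold change was -0.11 against -0.25 and 1 member was higher. Over all alternatives the list's adjusted p ranged from 0.0020 to 0.67 and that of CDC20.2 from 0.0051 to 0.054. Adjusted over the list alone, 5 were lower.

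**Figure D2:**
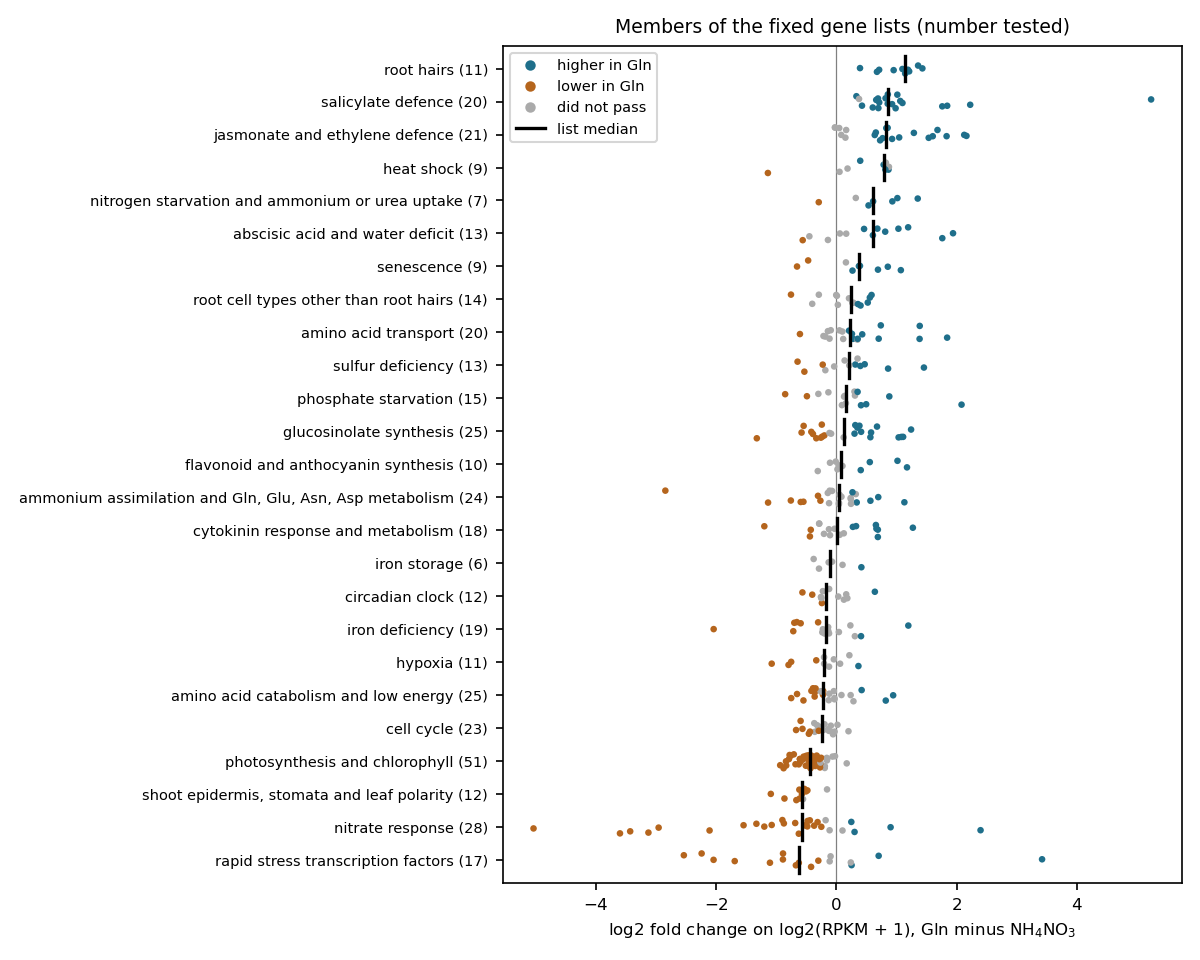
Log2 fold change (Gln minus NH4NO3, on log2(RPKM + 1)) of each tested member of the 25 gene lists, with the number tested in parentheses; blue points were higher, brown points lower, grey points did not pass the test, and black ticks are list medians. Medians run from 1.14 for root hairs to -0.63 for rapid stress transcription factors.

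**Figure D3:**
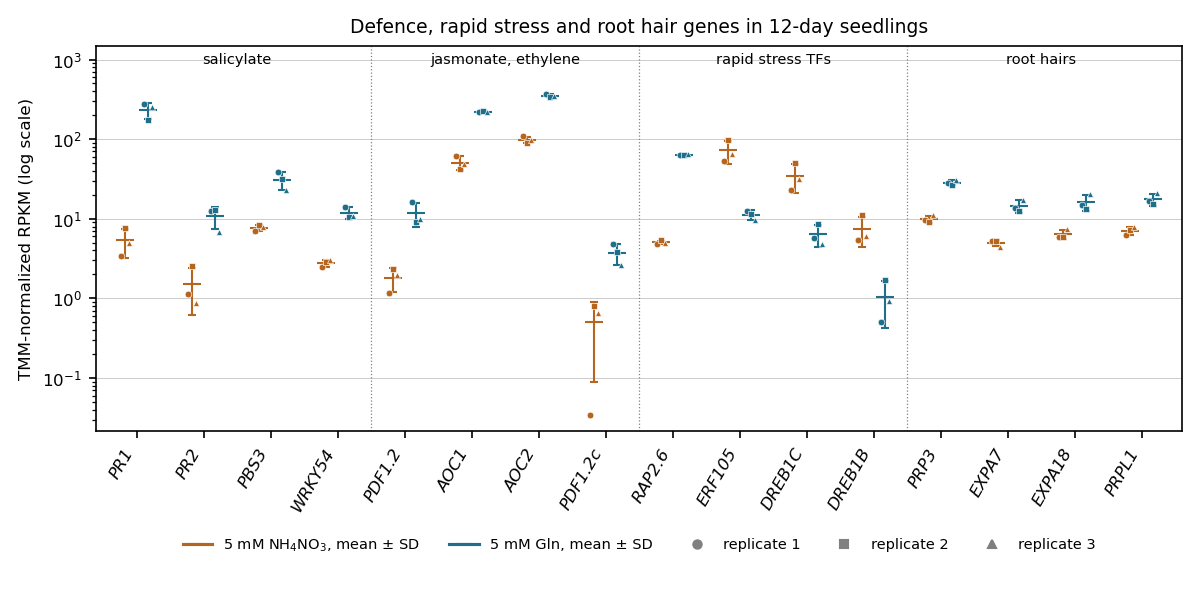
TMM-normalized RPKM on a log axis for named genes of the salicylate, jasmonate and ethylene, rapid stress and root hair lists on 5 mM NH4NO3 (brown) or 5 mM Gln (blue); points are the 3 replicates, and horizontal ticks with bars are the mean ± SD. PR1 shows the largest difference, and NH4NO3 replicate 2 (square) is the highest of its group for ERF105, DREB1C and DREB1B.

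By camera with the preset correlation, the other lists did not pass the threshold as lists, although members of each did. Because 41.2% of all genes tested were called, a share of called members near or below that does not set a list apart. This holds for the lists above as well, such as the cell cycle list. Glucosinolate synthesis genes split, with 12 of 25 higher and 10 lower (camera adjusted p = 0.49). CYP83B1, SOT16 and UGT74B1 rose from 170 ± 12.5 to 405 ± 40.5, from 114 ± 9.74 to 247 ± 11.4 and from 50.7 ± 5.22 to 108 ± 8.48 RPKM, and MYB28, the regulator of aliphatic glucosinolates, fell from 11.8 ± 1.21 to 4.08 ± 0.174 RPKM. In flavonoid and anthocyanin synthesis 4 of 10 rose (adjusted p = 0.096), namely PAL1 from 43.3 ± 4.08 to 98.7 ± 2.44 RPKM, C4H from 142 ± 0.843 to 288 ± 12.6 RPKM, CHS from 17.5 ± 1.49 to 26.3 ± 3.41 RPKM and PAL2 from 48.9 ± 1.54 to 65.0 ± 2.02 RPKM. The list passed with a filter at a mean of at least 5 RPKM (adjusted p = 0.031, the lowest of a range up to 0.95 over all alternatives). With no filter on low values 5 of 23 members were higher and 4 lower, with a median log2 fold change of -0.02. PAL1, PAL2 and C4H act in general phenylpropanoid synthesis and CHS at the entry to flavonoids, and 1 member was lower when adjusted over the list alone or without Gln replicate 2. Of 9 senescence genes 6 rose and 2 fell (adjusted p = 0.096). SAG13, NAP and SAG101 rose from 9.85 ± 1.26 to 21.9 ± 3.79, from 5.23 ± 0.647 to 10.3 ± 1.26 and from 18.7 ± 0.726 to 30.8 ± 2.23 RPKM, and SAG21 fell from 1297 ± 107 to 823 ± 53.2 RPKM. Without NH4NO3 replicate 2 or without Gln replicate 1 the number higher was 3, and without Gln replicate 3 the list passed (adjusted p = 0.041, the lowest of a range up to 0.64 over all alternatives). Of 9 heat shock genes 4 rose and 1 fell (adjusted p = 0.096), with HSP70 at 10.4 ± 2.73 and 19.4 ± 1.63, MBF1C at 20.25 ± 0.783 and 36.5 ± 3.60, HSP90.1 at 6.02 ± 0.912 and 11.1 ± 1.02 and HSP18.2 at 7.30 ± 0.721 and 2.80 ± 0.761 RPKM in NH4NO3 and Gln. MBF1C overlaps AT3G24503, at 95.3 RPKM over the 6 libraries, by 124 bases on the other strand. Of 11 hypoxia genes 4 fell and 1 rose (adjusted p = 0.096), and 2 were higher without NH4NO3 replicate 1. The falling genes included HB1, a haemoglobin that is also on the nitrate list, from 70.2 ± 4.16 to 32.8 ± 3.08 RPKM, SAD6 from 56.5 ± 8.90 to 31.9 ± 2.93 RPKM and HRA1 from 19.0 ± 2.4 to 10.8 ± 0.202 RPKM, and SUS1 rose from 7.65 ± 0.582 to 10.2 ± 0.922 RPKM.

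Among mineral nutrition lists, 6 of 19 iron deficiency genes fell and 2 rose (camera adjusted p = 0.096, or 0.011 with no filter on low values, the lowest of a range up to 0.66 over all alternatives). NAS1, a nicotianamine synthase, fell from 17.3 ± 0.810 to 3.45 ± 0.225 RPKM and the iron transporter IRT1 from 2.5 ± 0.409 to 1.17 ± 0.369 RPKM. F6'H1, of coumarin synthesis, rose from 47.2 ± 5.16 to 110 ± 12.4 RPKM. BHLH100 fell from 5.19 ± 1.69 to 2.75 ± 0.852 RPKM, with an adjusted p of 0.020 that became 0.067 without NH4NO3 replicate 1 and 0.069 without Gln replicate 2, and 0.055 with no filter on low values, in a range from 0.0021 to 0.069 over all alternatives. Without NH4NO3 replicate 1, 3 members of the list were lower. Of 6 iron storage genes 1 rose, FER3, from 78.6 ± 2.62 to 106 ± 15.5 RPKM (list adjusted p = 0.66), and 1 member was lower without NH4NO3 replicate 1 or without Gln replicate 3. Of 13 sulfur deficiency genes 5 rose and 3 fell (adjusted p = 0.37), including SULTR1;1 from 0.492 ± 0.186 to 3.07 ± 0.0980 RPKM, APR1 from 14.5 ± 1.98 to 27.0 ± 2.11 RPKM, SULTR1;2 from 22.3 ± 2.08 to 13.8 ± 0.460 RPKM and SULTR2;1 from 52.1 ± 1.72 to 35.7 ± 2.44 RPKM. The number higher was 3 without NH4NO3 replicate 3, without Gln replicate 2 or without Gln replicate 3. Of 15 phosphate starvation genes 5 rose and 2 fell (adjusted p = 0.17), with RNS1 from 1.29 ± 0.10 to 8.92 ± 2.69 RPKM, SPX1 from 7.59 ± 0.551 to 15.0 ± 3.28 RPKM and PHO1;H1 from 2.6 ± 0.276 to 1.0 ± 0.25 RPKM. The number higher was 3 without NH4NO3 replicate 2, without NH4NO3 replicate 3 or without Gln replicate 2, and the number lower was 1 without NH4NO3 replicate 2 and 4 after quantile normalization. AT4 rose from 12.3 ± 0.674 to 18.24 ± 5.76 RPKM (adjusted p = 0.041), a call lost without any 1 of NH4NO3 replicates 1 to 3 and Gln replicates 2 and 3, with no filter on low values, with quantile normalization, without the mean-variance trend or at an adjusted p of 0.01. Its adjusted p ranged from 0.0091 to 0.10 over all alternatives. Adjusted over the list alone, 6 sulfur genes and 7 phosphate genes were higher, and 3 of each were lower.

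Cytokinin genes went both ways, with 7 of 18 higher and 3 lower (camera adjusted p = 0.61). The cytokinin oxidases CKX5 and CKX3 rose from 1.81 ± 0.301 to 5.79 ± 0.872 RPKM and from 1.19 ± 0.243 to 2.52 ± 0.189 RPKM, ARR16 rose from 2.68 ± 0.704 to 4.92 ± 1.08 RPKM, and the synthesis gene IPT3 fell from 6.72 ± 1.13 to 2.35 ± 0.355 RPKM. CKX5 overlaps AT1G75440, at 64.2 RPKM over the 6 libraries, by 665 bases on the other strand, and is uncertain. Of 12 circadian clock genes 1 rose and 3 fell (camera adjusted p = 0.41). ELF4 rose from 24.5 ± 3.55 to 38.8 ± 6.58 RPKM, and PRR7 and ELF3 fell from 59.9 ± 5.21 to 40.1 ± 0.954 RPKM and from 16.29 ± 1.06 to 12.1 ± 1.53 RPKM. PRR5 fell from 14.3 ± 0.818 to 12.0 ± 1.00 RPKM (adjusted p = 0.042), a call lost in 12 of 20 alternatives: without any 1 of NH4NO3 replicates 1 to 3 and Gln replicates 1 and 3, with no filter on low values, median-of-ratios or library-total scaling, no mean-variance trend, array weights, the replicate block, and an adjusted p of 0.01. Its adjusted p ranged from 0.024 to 0.13 over all alternatives.

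Counts adjusted over the list alone equalled those over all genes for every list where no other count is given. With an estimated correlation between genes, camera called 0 of the 25 lists at an adjusted p under 0.05 and 4 at an unadjusted p under 0.05, against 11 with the preset correlation. Fry called 16, among them 9 of these 11 but not the rapid stress and cell cycle lists. The others that fry called were the flavonoid (fry adjusted p = 0.0015), ammonium assimilation (0.0079) and hypoxia (0.021) lists. It also called the phosphate (0.023), sulfur (0.023), senescence (0.044) and glucosinolate (0.047) lists. The estimated correlation was 0.0079 for the nitrate, -0.032 for the abscisic acid and -0.023 for the amino acid transport list, all below the preset 0.01. Their unadjusted camera p-values still went from 6.3e-10 to 0.0032, from 0.00071 to 0.023 and from 0.016 to 0.058. For these lists a larger correlation between genes is therefore not why the call was lost. Camera with an estimated correlation takes its p-value from the 4 degrees of freedom left after fitting the 2 groups. With the preset correlation it uses far more, so the same statistic gives a smaller p-value there. The loss of calls is therefore not a measure of correlation alone.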

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

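Voom on the implied reads, library totals, the removal of genes with shared reads and of list members lacking a symbol were chosen after seeing the data. The number of genes called lay within 1.5 times of 7942 under each alternative but an adjusted p of 0.01, which left 4912 (2072 of them lower, against 3816), as a stricter threshold must. Leaving out 1 replicate gave 5900 genes (without NH4NO3 replicate 2) to 7089, and 729 to 826 genes at 2-fold. The count at 2-fold followed the scale of the fold change: with a pseudocount of 5 it was 336 (272 higher and 64 lower, against 603 and 169), with a pseudocount of 0.1 the lower genes numbered 296. Voom on the implied reads, which changes both the scale and the weights, gave 1220, of which 324 were lower, with 8328 genes called in all; the cause was not tested. Under every alternative, at least 770 of the 772 genes stayed called, apart from 769 at an adjusted p of 0.01, 576 of the 576 still tested at a mean of at least 5 RPKM and 755 of the 755 still tested without shared reads. Quantile normalization made 45.5% of called genes higher in Gln, against 52.0%. Same-numbered replicates had deviations correlated at -0.07, -0.10 and -0.01, so no effect shared by equal numbers was seen. Whether equal numbers were grown or harvested together is not given in the labels. With the replicate number as a block 7274 genes were called, 772 at 2-fold, and no list changed its call. Of 120 named genes none changed direction under any alternative that tested it, and at most 7 lost (at an adjusted p of 0.01) and 1 gained a call under any 1 alternative. The number of lists called was 11, 10 to 12 when 1 replicate was left out and 8 to 13 under other settings of the gene test. It was 16 with fry and 0 by camera with an estimated correlation. For camera, the fewer degrees of freedom given above raise the p-value of every list. A larger correlation between genes was not the cause for the nitrate, abscisic acid and amino acid transport lists. For the other lists both causes were not told apart, and the reason for the higher count with fry was not tested. The cytokinin list, which was not called, had a mean log2 fold change of 0.09, -0.035 at a mean of at least 5 RPKM and, with 1 replicate left out, 0.013 (without NH4NO3 replicate 2, where the camera direction was down) to 0.147; the cause was not tested. Camera was not run with robust eBayes. A count test on the implied reads was listed before the data were examined, for the case that whole reads could be recovered. It was not run, although nearly all implied low reads were whole, because count tests were kept to deposited counts. In the simulation, most genes given the smallest change stayed undetected with 3 replicates. The adjustment was stricter there than in the real data, so this share does not carry over to them.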

Other observations

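The families, the gene FT, the split of the glucosinolate list and every test below other than the count of other splits were chosen after the data were seen. Several families that the fixed lists do not hold moved mostly one way. Among 177 families of at least 10 tested genes with the same product name, 13 passed camera with the preset correlation and none with an estimated correlation (adjusted p = 0.80 for those named here). All 11 proline-rich extensin-like genes were higher, with a median log2 fold change of 1.23 (camera adjusted p = 4.5e-06), although 3 of the 11 have multi-read ratios above 0.1 and are uncertain. None of these 11 is on the root hair list. Of 53 peroxidases 29 were higher and 6 lower (adjusted p = 0.00047), and of 19 berberine-type oxidases 12 were higher and 2 lower (adjusted p = 0.00073). Of 23 NPH3 family genes, relatives of a protein of blue-light signalling, 15 were lower and 0 higher (adjusted p = 0.00070), and of 38 pectin lyase-like genes, another cell wall family, 18 were lower and 3 higher (adjusted p = 0.013). Under quantile, median-of-ratios and library-total scaling the higher counts were 11 for the extensins, 27 to 31 for the peroxidases and 12 for the oxidases, and the lower counts were 15 to 16 for the NPH3 family and 16 to 18 for the pectin lyase-like genes. FT, which encodes the mobile flowering signal, fell from 12.2 ± 0.146 to 2.27 ± 0.0850 RPKM (SD, n = 3 per group), a log2 fold change of -2.02 ± 0.08 (SE, limma adjusted p = 3.8e-07), and was lower in all 3 Gln libraries than in any NH4NO3 library.

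A hypothesis on the mixed glucosinolate list was that its indolic and aliphatic branches moved apart. Of 8 indolic members 7 were higher and 1 lower, and of 15 aliphatic members 3 were higher and 9 lower. The rest of the 25 tested members were assigned to neither branch and left out, and they were higher in Gln. Their mean log2 fold changes, 0.56 and -0.19, differed by 0.74 (95% bootstrap interval 0.29 to 1.16; 2-sided permutation test over genes, p = 0.0023), and by 0.72 to 0.74 under the other scalings. The values are in line with the hypothesis, but genes of a branch are not independent replicates.

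The 6 libraries allow only 10 splits into 3 and 3, too few for a share of splits under 0.05. The real split called 7942 genes by limma, 772 of them at 2-fold, and 1 of the 10 splits, the real one, gave as many in each case. The highest number in the other 9 was 0, with 119 to 379 genes at an unadjusted limma p under 0.05 against 9598. Each of these 9 splits mixes both media in each of its groups, so the difference between media adds to the residual spread. Few calls were thus fixed in advance, and the 0 does not measure what chance gives. For the lists 2 of the 10 splits gave as many as the real one: camera with the preset correlation called 11 lists on the real split and as many as 12 on another, with 5 the lowest.

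Root hair genes were higher in Gln while photosynthesis and shoot genes were lower. A larger share of root with an unchanged mix of root cell types would raise all genes expressed only in roots alike in the Gln seedlings. Instead, root hair genes rose by 0.90 more (log2) than genes of other root cell types (95% bootstrap interval 0.65 to 1.17, permutation test over genes p = 2.0e-05). The difference was 0.58 to 1.07 over 14 settings. It argues against a larger root share of unchanged mix as the only cause, provided that both lists hold genes expressed in roots alone. A gene also expressed in shoots would rise less. Expression outside roots was not measured, so the difference does not decide this. Genes of a list are not independent replicates, with estimated correlations of 0.40 for root hair genes and 0.41 for the other root genes. The permutation p is therefore likely too small. A larger root share with a changed mix of root cell types stays open, because the lists mark different cell types. A smaller share of shoot would lower both shoot lists alike, and this stays open: the mean of photosynthesis genes was 0.155 above that of the shoot epidermis, stomata and polarity genes (interval 0.02 to 0.30; permutation p = 0.039), but -0.03 with a pseudocount of 5 (p = 0.63), and 8 of 14 settings passed 0.05. A changed root and shoot share as part or all of the cause, and more or longer root hairs on Gln, stay open and were not measured.

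Salicylate defence genes were higher in Gln. Contamination or stress of some but not all Gln samples was argued against by the 20 tested members of the list, of which 20, 19 and 19 lay above every NH4NO3 library in Gln replicates 1, 2 and 3. In the Gln library with the lowest values, replicate 3, their median lay 0.55 (log2) above the highest NH4NO3 value of each gene (95% bootstrap interval over genes 0.35 to 0.80), and it lay 0.61 and 0.82 above in Gln replicates 2 and 1. Genes of the list are not independent replicates, with an estimated correlation of 0.37, so the interval is likely too narrow. The calls of these genes came from the same libraries, so high values in most of them were likely beforehand. Reads shared between paralogs stay open: without genes of a multi-read ratio above 0.1 the list still had 20 members tested and 19 higher, but no member exceeded that ratio, which is not defined and is 0 for near-identical copies such as AOC1 and AOC2. A microbe or a stress common to all Gln samples, the absence of nitrate or ammonium, and an effect of Gln itself stay open. They were not tested, since the design gives no way to part them.

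Rapid stress transcription factors were lower in Gln, and 9 of the 11 lower genes were highest in NH4NO3 replicate 2 within their group. High values in that library alone do not account for the pattern, because 9 genes were called lower without it. Sampling of the 2 media at different times of day could shift such genes. The median absolute log2 fold change of the clock list lay at percentile 58.9 of 10000 random lists matched on expression, which neither excludes nor supports such a shift. The labels give no time of harvest, and handling before harvest stays open as well.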
